A study of Mus musculus with 23 samples.

How the data were processed

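The series holds 23 Affymetrix mouse expression arrays. Per the labels, 19 are from individual subcutaneous tumours that grew in Balb/c nude mice from embryonic mesenchymal cells carrying a retrovirus for the ASPSCR1-TFE3 fusion, and 4 are from a mixture of 10 normal mouse tissues (liver, kidney, heart, skeletal muscle, skin, lung, ovary, colon, brain and bone marrow). The mice that gave the tissues of the mix were 5 weeks old. Per the labels' protocols, total RNA was column-purified and 100 ng was labelled as biotinylated cRNA. The deposited table gives log2 values for 45141 probe sets. MAS5 is the only tool in the submitters' processing notes, with no version; the normalization between arrays, the centring and the log base are not given in the sources used here.

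Every one of the 45141 probe sets has a median of exactly 0 over the 23 arrays, so the deposited log2 values are centred per probe set and absolute levels are not given. The array medians lie between -0.09 and 0.08. Base 2 was inferred from the values and is not proved by them. The rounding steps of the 914125 values large enough to show one are all those of a stored level of 2 or more (100%). The largest range within a probe set is 9.84. Such steps show the size of a stored level and not its log base. They give the octave of each probe set's median level: 11034 probe sets lie from 2 to 4, 25852 from 4 to 8 and 8255 at 8 or more. Of the 8255, 189 lay on a step of 16 or more, which was taken as chance. Of the array's nonspecific background controls, 16 lie in the lowest octave and 7 in the next. No detection calls were used, so a large decrease may be a lower bound where the tumours lie at background. For arrays, their number limits the precision. Because 19 of the 23 arrays are tumours, a value of 0 is close to the tumours' own median.

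Gene names came from the platform's annotation, with Entrez numbers looked up in a RefSeq gene table (GRCm38.p6, used for names only; no coordinates are printed). Of the probe sets, 28898 have 1 gene symbol, 551 have several and 15692 have none listed, and those with several or none named no gene. Among the 28898, 28689 matched the RefSeq table by Entrez number. A gene's value was the mean of its probe sets, which gave 17097 genes, 7180 of them with 2 or more probe sets. Probe sets of 8 genes were called in opposite directions, and of 1117 called genes with 2 or more probe sets 522 had all of them called the same way, so for the others the mean covers probe sets that did not pass. Every column of the table was used.

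The design written before the data were examined could not be followed in 4 points, because the values turned out to be centred. A pseudocount has no meaning on them, a filter on low signal and a choice of the brightest probe set need levels, and a variance trend on the mean needs them too. The main setting therefore has no filter, averages the probe sets and uses eBayes without a trend. Quantile normalization was not run on centred values. Tumours were compared with the mix in limma 3.58.1 (R 4.3.3) by lmFit and eBayes over all 23 arrays, with Benjamini-Hochberg adjustment over all genes. A gene was called at an adjusted p under 0.05 and a log2 difference of at least 1 in size. All differences are tumour minus mix. The labels do not say whether the 4 mix arrays came from separate pools, and they correlate at 0.990 to 0.995, so p-values measure the spread between these arrays, which for the mix may be technical. A tissue that makes up a part of the mix is diluted in it.

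Gene lists, 36 in number, were fixed before the data were examined and tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and fry as alternatives. The relations tested across tumours, 10 between list scores or genes, were also fixed. A score is the mean z-score of a list's members among the 19 tumours, without genes on both lists. Pearson and Spearman coefficients have two-sided permutation p-values from 100000 resamples, adjusted over the 10. Genes are named by a rule fixed beforehand: the fusion partners, the 10 largest increases and decreases among called genes whose groups do not overlap, up to 3 called genes per list and direction, 11 genes named whatever the result, the 10 genes with the largest SD among tumours, and uncalled members given to show that a list is mixed. Single values were compared by exact permutation over the 8855 splits of the arrays.

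The fit was tested on simulated data with the 17097 genes. Of 100 genes changed by 1.5 on the log2 scale, 96% were called, as were 100% of 100 genes changed by 3, and 0 of 16897 unchanged genes. The 1 list made to shift had an adjusted p of 5e-29 by camera, and 1 of 35 other lists was called. Every gene and array was drawn independently, so the simulated data hold no correlation between genes and treat the mix arrays as separate samples. How often lists are called falsely in the real arrays is therefore not shown by it.

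The array's own controls set 4 tumours apart in a way that the labels do not name. In tumours 18, 20, 22 and 23 the dap controls, bacterial poly-A RNAs normally added before labelling, lay between -4.49 and -3.89, against -1.90 or higher on all other arrays. The probe sets for 18S ribosomal RNA lay between -6.38 and -4.78 there, against -1.30 or higher elsewhere. Whether these 4 were labelled separately is not known. Values given within the 15 tumours compare the others with the mix; these 15 are not uniform either, since tumours 5, 6 and 7 had 18S values between -1.30 and -1.05. Alternatives covered scaling, the choice of probe set, the variance model, array weights, an exact rank-sum test, the mix averaged to 1 sample, fold thresholds, the replicate number as a block and each array left out. Alternatives chosen after seeing the data were leaving out these 4 tumours, a term for them in the fit, leaving out 7 tumours with low 18S values, 2 filters on level and the probe set with the largest SD. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used, with matplotlib 3.10.9 for the plots.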

Results

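The arrays compared 19 mouse tumours driven by ASPSCR1-TFE3, the gene fusion found in human alveolar soft part sarcoma, with 4 arrays of a mixture of 10 normal mouse tissues. The comparison asks which transcripts are higher or lower in the tumours than in the tissue mix. Values are log2 values centred on each probe set's median over the 23 arrays, so differences between groups can be read and levels cannot.

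Of 45 lysosomal and autophagy genes, 27 were higher in the tumours than in the mix, and most of the markers measured for liver, bone marrow, colon, kidney, lung, brain, skin and heart were lower. Of 17097 genes, 1179 were called higher and 1968 lower in tumours (limma, adjusted p under 0.05 and a log2 difference of at least 1), so 37.5% of the calls were higher. The groups did not overlap for 976 of the higher and 1716 of the lower genes, and for 5278 of all 17097 genes. Chance would separate 0.0226% of genes if the 4 mix arrays were separate samples, and far more if they came from one pool. The largest increases were Aqp3, an aquaglyceroporin (6.02 ± 0.14, log2 difference ± SE, 64.8-fold), Gpr143, a melanosomal receptor (5.99 ± 0.23), Hapln1, a hyaluronan link protein (5.90 ± 0.76), and Gpnmb, a glycoprotein of lysosomes and melanosomes (5.60 ± 0.59, 48.4-fold). Gm3715, Hhipl1, Tspan10, Car13, Cabp1 and Mlana followed, with differences of 5.45 to 5.04. The 10 largest decreases were transcripts of liver, lung and kidney or of gut, led by Serpina1a (-9.11 ± 0.05), Alb (-8.97 ± 0.10), the club cell gene Scgb1a1 (-8.78 ± 0.37), Fabp1 (-8.76 ± 0.23) and Umod (-8.71 ± 0.04), with Cyp3a11, Serpina1c, Ttr, Cltrn and Apoc3 between -8.67 and -8.55. Of the 13 probe sets of these 10 genes, 9 had a median in the octave that holds most background controls and 4 in the next, so the size of these decreases may be limited by background. The increases may be limited in the same way by background in the mix: of their 15 probe sets, 14 had a median of 8 or more and 1, that of Cabp1, a median from 4 to 8 with the mix 5.11 lower, so folds are of measured values only. Within the 15 tumours without low poly-A controls, 1172 genes were called higher and 1943 lower. The median difference over all genes was 0.12; with every array scaled to one median it was 0.04, and 1022 genes were called higher and 2109 lower. With the mix averaged to 1 control sample, the log2 differences stayed the same and the error came from the spread between tumours alone. That spread was larger than the spread between mix arrays (median SD over all genes of 0.24 against 0.07). A call lost in this fit therefore does not measure uncertainty in the mix. Many named genes lost their call in it. Among them were Mlana, Ctsh, Met, Ptgds, Tgfb1, Cxcl12, Creld2, Atf3, Ier3, Mki67, Ccna2, Ube2c, Adm, Ndrg1, Aldoc, Shox2, Comp, Dlx5, Col11a1, Dpt, Col6a1, Col6a2, Mmp13, Mmp12, Mmp9, Plau, Myrip, Ddr2, Sfrp2, Bmp4, C1qc, Cd68, Usp18, Adipoq, Xist and the muscle genes Tnnc2, Tnnt3, Myl1 and Mylpf.

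**Figure D1:**
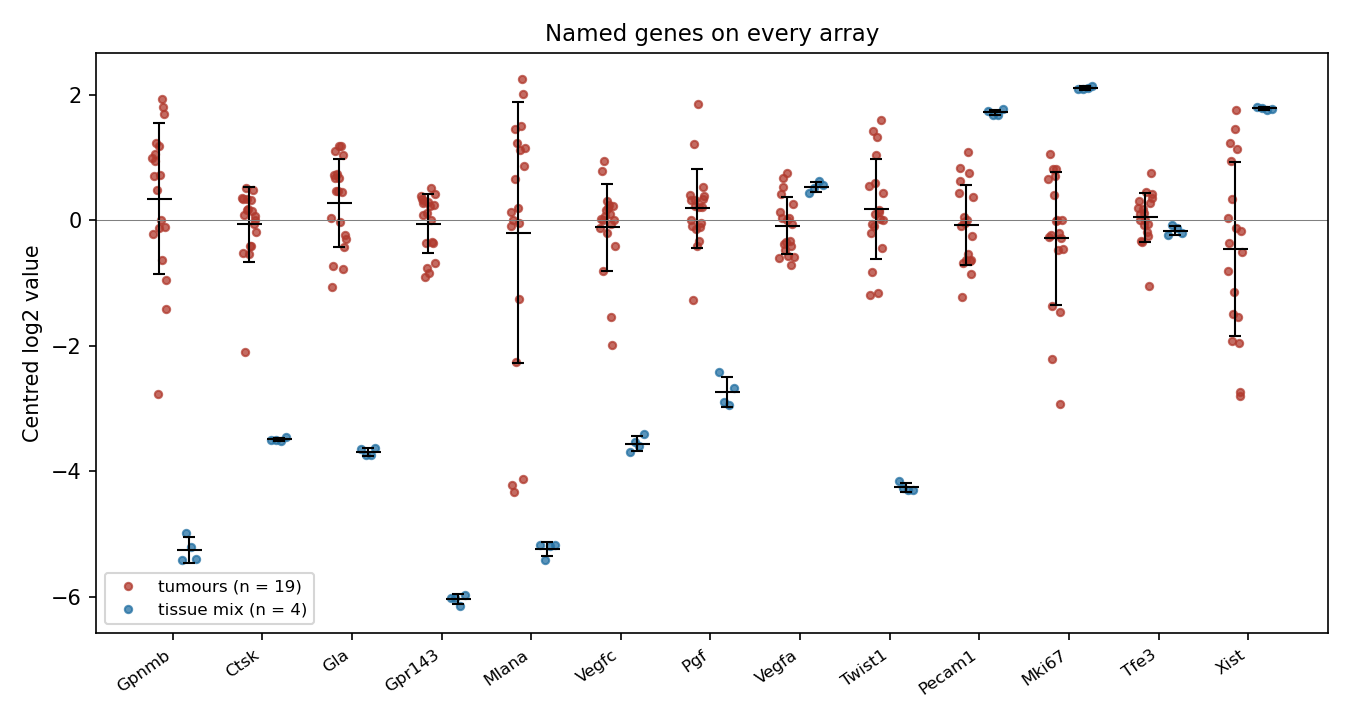
Centred log2 values of 13 named genes on each array (points), with the mean and SD of the 19 tumours (red) and the 4 mix arrays (blue). Gpnmb, Ctsk, Gla, Gpr143, Vegfc, Pgf and Twist1 lie higher in the tumours, Pecam1 and Mki67 lower, and Tfe3 overlaps between the groups.

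Of the 36 gene lists, 17 were shifted by camera at the preset correlation. With an estimated correlation 9 were, namely lysosome upward and liver, bone marrow, colon, kidney, lung, brain, skin and heart downward. Other splits of the 23 arrays also called many lists at the preset correlation: 17 of 100 splits, the real one included, called 17 or more, against 1 of 100 for the 9. The mix arrays correlate at 0.990 or more, so the lead of the real split in the latter was largely fixed in advance. A filter kept genes whose level reached 8 in the higher group, judged by the lowest level that the octave allows. It left out more of the genes lower in tumours, since 56.6% of calls were then higher, against 37.5% without it. A shift lost under this filter therefore does not describe well-expressed genes as such. Among the genes kept, 7 of the 17 lists were no longer shifted. These were heart (mean -0.57), melanocyte pigmentation (1.29) and receptor tyrosine kinases (0.093), each at adjusted p = 0.629, and endothelial cells (-0.39, adjusted p = 0.613). Vesicle trafficking (-0.95) and the unfolded protein response (0.69) had adjusted p = 0.339, and adipose (-1.66) adjusted p = 0.309. Counts of members adjusted over the list alone were those given for all genes, except 6 instead of 5 higher for the genes reported in alveolar soft part sarcoma and 18 instead of 17 lower for skeletal muscle.

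Of the 45 lysosomal and autophagy genes measured, 27 were called higher and 1 lower, with a median difference of 1.37 (camera adjusted p = 1.4e-10, and adjusted p = 0.0176 with an estimated correlation). The list's mean was above all 4 mix arrays in 19 of 19 tumours, at 0.04 ± 0.11 (SD, n = 19) against -1.20 ± 0.02 (SD, n = 4), and its median within the 15 tumours without low poly-A controls was 1.28. The leading members were Gpnmb, the lysosomal galactosidase Gla (3.96 ± 0.34, 15.6-fold) and Ctsk, which encodes cathepsin K (3.43 ± 0.29, 10.8-fold). Ctsh, another cathepsin, was the member called lower (-1.43 ± 0.52); that call was lost without mix array 2 (-1.41, adjusted p = 0.0567), 3 (-1.42, adjusted p = 0.0557) or 4 (-1.41, adjusted p = 0.0564). Ctss (-0.02) and Lamp2 (-0.65) were not called, so the list was not uniform.

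Genes linked to alveolar soft part sarcoma moved both ways. This list includes genes that publications on this mouse model named, so it is not independent evidence. Of 14 measured, 5 were called higher and 3 lower, and the list was not shifted (adjusted p = 0.58). Gpnmb and Ctsk are on this list too, and Upp1, uridine phosphorylase, was also higher (1.90 ± 0.18). Sv2b (-1.98 ± 0.09) and Ptgds (-2.71 ± 0.52) were lower. The mean for Met, a receptor tyrosine kinase, was called lower (-1.33 ± 0.24), but its probe sets differed. The one with the higher median level was not called (0.21, adjusted p = 0.0759) and the other was lower (-2.87). Rab27b (-1.28 ± 0.81, adjusted p = 0.181) and Sytl2 (1.21 ± 0.54, adjusted p = 0.0579), both of secretory vesicle trafficking, did not pass; Sytl2 passed without tumour 18 (1.41) and within the 15 tumours (1.32), Rab27b without tumour 6 (-1.58), and both with the exact rank-sum test (adjusted p = 0.0057 and 0.0207). Among the MiT transcription factors and fusion partners, the mouse probe sets for Tfe3 (0.21 ± 0.19, adjusted p = 0.356) and Aspscr1 (0.41 ± 0.13, adjusted p = 0.00851) were not called. The Aspscr1 value is the mean of 2 probe sets that differed, at 0.90 (limma adjusted p = 3.8e-05) and -0.08 (limma adjusted p = 0.696). Whether the probe sets for Tfe3 and Aspscr1 can detect the retroviral fusion is not known from the sources used here, so they check nothing about it. Of the 5 members 1 was called, Tfec (-1.05 ± 0.18), and that call was lost without tumour 18 (-0.99), without mix array 4 (-0.97) and within the 15 tumours (-0.94). The list did not shift (adjusted p = 0.84); its median was 0.21, its mean -0.09 and its camera direction down.

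Of 28 secreted angiogenic factors, 10 were called higher and 3 lower, with a median of 0.54, and the list was not shifted (adjusted p = 0.377). The lymphangiogenic factor Vegfc (3.45 ± 0.34), placental growth factor Pgf (2.93 ± 0.31) and Tgfb1 (1.95 ± 0.53) were the largest increases, and Fgf1 (-2.87 ± 0.19), Ang (-2.70 ± 0.28) and Cxcl12 (-1.82 ± 0.35) the decreases. A part of the increase of Tgfb1 came from the 4 tumours with low poly-A controls. It was 2.04 higher there than in the other 15 tumours (limma adjusted p = 0.00142). Of the 3 probe sets of Cxcl12, 1 was not called (0.39). Vegfa was not called (-0.62 ± 0.22, adjusted p = 0.0222, a difference under the threshold), nor was Pdgfb (0.91 ± 0.23, adjusted p = 0.00199), which passed on its most variable probe set (1.28). Of 24 endothelial markers, 10 were called lower and 1 higher, with a median of -0.88 (adjusted p = 0.00253, and adjusted p = 0.51 with an estimated correlation; -0.87 within the 15 tumours). The angiopoietin receptor Tek (-3.52 ± 0.38), the junction gene Cldn5 (-2.97 ± 0.33), Vwf (-2.77 ± 0.35) and Pecam1 (-1.80 ± 0.31) were lower, while Emcn (0.41) and Plvap (0.38) were not called. Flt4, which encodes the main Vegfc receptor, was higher (1.02 ± 0.16), and fell under the threshold without tumour 20 (0.99), 22 (1.00) or 23 (1.00) or mix array 1 (1.00), within the 15 tumours (0.90) and with arrays scaled to one median (0.94). Of 14 pericyte and smooth muscle genes, 6 were lower and 0 higher, led by the contractile genes Cnn1 (-5.83 ± 0.10), Myl9 (-4.26 ± 0.35) and Myh11 (-2.78 ± 0.12); the list's median was -0.31 (adjusted p = 0.0161, and adjusted p = 0.271 with an estimated correlation; -0.32 within the 15 tumours).

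**Figure D2:**
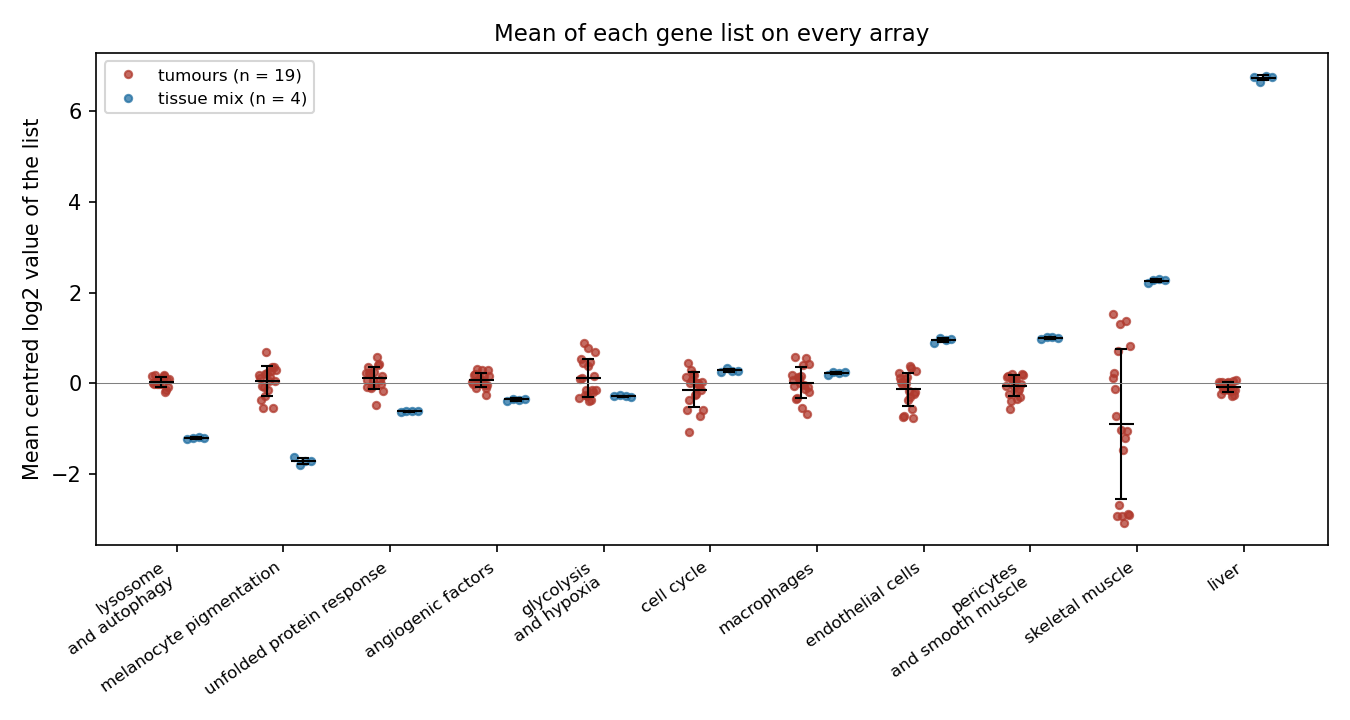
Mean centred log2 value of 11 gene lists on each array (points), with the mean and SD of the 19 tumours (red) and the 4 mix arrays (blue). The lysosome list lies above the mix in all 19 tumours and the endothelial list below it, and the skeletal muscle list ranges from -3.07 to 1.54 among tumours.

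Of 12 melanocyte pigmentation genes, 4 were called higher and 0 lower (median 0.46, mean 1.76, adjusted p = 0.0161, and adjusted p = 0.181 with an estimated correlation; median 0.43 within the 15 tumours). These were Gpr143, Mlana (5.04 ± 1.02), the melanocyte channel gene Trpm1 (4.00 ± 0.44) and Tyrp1 (3.84), the last named after its value was seen. The melanin synthesis genes Tyr (0.25) and Dct (-0.23) were not called, nor was the melanosome matrix gene Pmel (0.97 ± 0.60, adjusted p = 0.167; 1.09 within the 15 tumours, adjusted p = 0.163). Of 20 genes of the unfolded protein response, 7 were higher and 0 lower (median 0.54, adjusted p = 0.0377, and adjusted p = 0.51 with an estimated correlation), among them Ddit3, which encodes the stress factor CHOP (2.90 ± 0.21), Sdf2l1 (1.74 ± 0.28) and Creld2 (1.71 ± 0.49); the chaperone gene Hspa5 (0.32) was not called. Of 17 immediate early and stress genes, 2 were higher and 5 lower (adjusted p = 0.99; median 0.05, mean -0.13). The orphan nuclear receptor gene Nr4a1 (3.41 ± 0.29) and Atf3 (1.48 ± 0.44) were higher, and Ier3 (-1.72 ± 0.40) and Ier2 (-1.25 ± 0.18) lower.

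Cell cycle genes were not raised against the mix, which contains bone marrow and other dividing tissues. Of 36 measured, 5 were called lower and 0 higher, with a median of -0.39 (adjusted p = 0.0852). Mki67 (-2.39 ± 0.52), Ccna2 (-1.56 ± 0.30) and Ube2c (-1.28 ± 0.30) were lower, and Mcm2 (0.70) was not called. Of 29 glycolysis and hypoxia genes, 5 were higher and 2 lower (median 0.47, adjusted p = 0.322). Hexokinase gene Hk2 (3.19 ± 0.34), Egln3 (1.88 ± 0.20) and Adm (1.81 ± 0.64) were higher, Ndrg1 (-2.14 ± 0.48) and Aldoc (-1.47 ± 0.26) lower. Of 32 oxidative phosphorylation genes limma called 0 (median 0.15, adjusted p = 0.248); 14 had an unadjusted p under 0.05, and the largest difference was 0.81 in size. Fry, which does not compare the list with other genes, gave adjusted p = 0.0425 upward.

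Among 32 limb and skeletogenic mesenchyme genes, 6 were higher and 1 lower (median 0.20, adjusted p = 0.348). The limb transcription factor genes Shox2 (4.74 ± 1.00) and Twist1 (4.44 ± 0.39) and the cartilage matrix gene Comp (1.99 ± 0.62) were higher, and Dlx5 lower (-1.70 ± 0.44); Shox2 was not called with a variance trend (adjusted p = 0.197). Of 25 fibrillar matrix and fibroblast genes, 2 were higher, the fibroblast protease gene Fap (4.16 ± 0.62) and Col11a1 (2.93 ± 0.79), and 5 lower, among them Dpt (-2.37 ± 0.58), Col6a1 (-2.08 ± 0.55) and Col6a2 (-1.84 ± 0.46); Col1a1 (-0.39) was not called (list adjusted p = 0.515). Of 14 basement membrane genes, 3 were lower and 0 higher (adjusted p = 0.157), including Col4a3 (-2.58 ± 0.07) and Col4a5 (-2.39 ± 0.28). Of 22 matrix protease genes and inhibitors, 5 were higher and 3 lower (adjusted p = 0.871; mean 0.22), with the collagenase gene Mmp13 (3.85 ± 1.22), the inhibitor gene Timp1 (3.57 ± 0.24) and Mmp12 (2.71 ± 0.80) higher and Mmp9 (-2.79 ± 0.62), Timp3 (-1.87 ± 0.27) and Plau (-1.64 ± 0.31) lower.

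Of 26 vesicle trafficking and exocytosis genes, 2 were higher and 7 lower (median -0.11, mean -0.58, adjusted p = 0.0199, and adjusted p = 0.104 with an estimated correlation; median -0.09 within the 15 tumours). Myrip (1.95 ± 0.44) and Rab27a (1.49 ± 0.20), which work together in organelle transport, were higher, while the granin family genes Chgb (-4.42 ± 0.15) and Scg2 (-3.32 ± 0.16) and the neuroendocrine gene Scg5 (-5.03 ± 0.41) were lower. Of 23 receptor tyrosine kinases, 3 were higher and 6 lower (median -0.36, adjusted p = 0.0183, and adjusted p = 0.181 with an estimated correlation; -0.33 within the 15 tumours). Ret (2.71 ± 0.35) and the collagen receptor gene Ddr2 (1.22 ± 0.23) were higher, Erbb3 (-2.01 ± 0.09) and Ntrk2 (-1.33 ± 0.16) lower. Igf1r (1.01 ± 0.33) was the other one called higher. It fell under the threshold with arrays scaled to one median (0.93), with the random block (0.98) and without any of several single arrays, such as tumour 12 (0.96). With the probe set of largest interquartile range it was 0.67 (limma adjusted p = 0.328). These means hide probe sets that differ. For Erbb3 1 of 2 was lower (-4.19) and the other not called (0.16). For Ntrk2 3 of 7 were called. The list was not shifted with the probe set of largest interquartile range (mean -0.67, adjusted p = 0.067). Of 30 genes of Wnt, Notch, BMP and TGF-beta signalling, 3 were higher and 9 lower (adjusted p = 0.156), with Bmp7 (2.57 ± 0.32) and Sfrp2 (2.23 ± 0.64) higher and the inhibitory Smad6 (-3.50 ± 0.24) and Bmp4 (-2.67 ± 0.51) lower.

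Macrophage markers went both ways. A fall against a mix that holds bone marrow and liver does not show that the tumours held fewer macrophages. Of 20, 4 were called higher and 4 lower (median 0.01, mean -0.21, adjusted p = 0.755). The complement gene C1qc (1.53 ± 0.32) and Cd68 (1.51 ± 0.40) were among those higher, and Arg1, also a liver gene (-5.75 ± 0.36), Lyz2 (-1.75 ± 0.29) and Itgam (-1.54 ± 0.12) lower; Csf1r (-0.06) was not called. Of 18 T and NK cell genes 1 was lower, Cd3d (-1.63 ± 0.14) (adjusted p = 0.84; median 0.08, mean -0.08), and of 10 B cell genes 2 were lower, Jchain (-5.60 ± 0.64) and Cd79b (-1.32 ± 0.12) (adjusted p = 0.15). Of 18 checkpoint and antigen presentation genes, 2 were higher, the class I genes H2-K1 (1.56 ± 0.23) and H2-D1 (1.29 ± 0.13) (adjusted p = 0.255). Of 15 interferon response genes, 1 was higher, Usp18 (2.42 ± 0.44), and 5 lower, among them Rsad2 (-2.68 ± 0.13) and Ifih1 (-1.57 ± 0.23) (adjusted p = 0.0732).

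Markers of the organs in the mix were lower in tumours, except those of ovary. Whether the ovary markers rose above background in the mix was not tested, so this exception does not show ovary-like expression in the tumours. The counts called lower were 17 of 18 for liver, 16 of 17 for bone marrow, 14 of 16 for colon, 13 of 18 for brain, 13 of 15 for kidney, 10 of 13 for lung, 10 of 19 for skin, 9 of 15 for heart and 17 of 20 for skeletal muscle, with 0 called higher in any. The medians ran from -7.84 for liver to -1.09 for skin. All of these lists were shifted, with adjusted p from 2e-26 for liver to 0.00092 for skeletal muscle. With an estimated correlation the shift held for each except skeletal muscle (adjusted p = 0.553), heart being closest to the threshold (adjusted p = 0.0459). The heart list was also not shifted among genes whose level reached 8 by its lower bound (mean -0.57, adjusted p = 0.629). Examples are the neutrophil granule gene Ngp (-7.62 ± 0.11), the synaptic gene Snap25 (-7.99 ± 0.09), Krt14 of skin (-5.66 ± 0.05) and the surfactant gene Sftpc (-8.37 ± 0.31). Of 18 ovary genes limma called 0 (median 0.24, adjusted p = 0.105); 13 had an unadjusted p under 0.05, with a largest difference of 0.44 in size, and fry gave adjusted p = 5.1e-05 upward. Of 12 adipose genes, 7 were lower, including Adipoq (-3.66 ± 1.05), and 1 higher, Pparg (2.08 ± 0.29) (adjusted p = 0.0161, and adjusted p = 0.271 with an estimated correlation).

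Among the 36 lists, the mean of skeletal muscle transcripts had the largest SD across tumours. The list's mean was -0.89 ± 1.65 (SD, n = 19) and ranged from -3.07 to 1.54, against 2.22 to 2.30 on the mix arrays. Acta1, Tnnc2, Tnnt3, Myl1 and Mylpf are 5 of the 10 genes with the largest SD; Acta1 differed from the mix by -3.78 ± 1.69 and was not called (adjusted p = 0.0596), but passed without tumour 2 (-3.97) or 17 (-3.96), with the exact rank-sum test (adjusted p = 0.00073) and with array weights by group (adjusted p = 0.00137) or per array (adjusted p = 0.00192). Over all genes the median SD was 0.24 among tumours and 0.07 among mix arrays, and 452 genes had an SD of 1 or more among tumours and 0 among mix arrays.

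The tumours and the mix differed in the 3' minus 5' value of the Actb control, and no difference was found for Gapdh. Each probe set is centred on its own median over all arrays. These values therefore compare arrays with each other and do not show whether the RNA was intact. The 3' minus 5' difference of the Gapdh control was 0.02 ± 0.12 (SD, n = 19) in tumours and -0.03 ± 0.01 (SD, n = 4) in the mix (two-sided exact permutation p = 0.378). For Actb it was -0.01 ± 0.17 and -0.33 ± 0.02 (exact permutation p = 0.00102). Between the 4 tumours with low poly-A controls and the other 15, limma called 111 genes higher and 90 lower in the 4. Tgfb1 (2.04) and Plau (-1.04), both named above, were among these genes. The log2 differences with and without these 4 tumours correlated at 0.998 across genes, which are not independent replicates.

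Of the 10 relations fixed beforehand, 0 passed across the 19 tumours after adjustment, and 2 had an unadjusted permutation p under 0.05. The endothelial score and that of pericytes and smooth muscle had r = 0.548 (permutation p = 0.0157, adjusted p = 0.157; rho = 0.439, permutation p = 0.0634), 0.374 without the 2 tumours farthest from the median and 0.540 within the 15 tumours. With glycolysis and hypoxia the endothelial score had r = -0.481 (permutation p = 0.0384, adjusted p = 0.192; rho = -0.530, permutation p = 0.0215), -0.627 without the 2 farthest and -0.622 within the 15. Gpnmb and the lysosome score without it had r = -0.331 (permutation adjusted p = 0.326), -0.585 without the 2 farthest and -0.315 within the 15. Vegfa and the endothelial score had r = -0.382 (permutation adjusted p = 0.264), -0.300 without the 2 farthest and -0.447 within the 15. The other 6 had r between -0.03 and 0.43. Tumour 17 decides this count: without it 4 relations passed, namely macrophages with lysosome (r = 0.736, adjusted p = 0.0037), the endothelial score with pericytes (0.584) and with glycolysis (-0.555), and Vegfa with the endothelial score (-0.548). Macrophages and lysosome had r = 0.160 without tumour 18, 0.067 without the 2 tumours farthest from the median and 0.095 within the 15 tumours, so this relation rests on which tumours are included.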

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

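The tests of explanations here and under the other observations were chosen after the values they use had been seen, and so were the counts over other splits of the arrays; the search for outlying mix arrays was planned.

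Among 150 named genes and 36 list means, 14 had 1 of the 4 mix arrays far from the other 3, judged by the gap to its nearest neighbour as a share of the range, where chance gives about 9.3. The shares were 0.968 for Aldoc, 0.884 for Ctsk and 0.835 for Myl1 (mix array 4), 0.869 for Car1, 0.834 for Cd3d, 0.894 for Ctsh, 0.868 for Hspa1b, 0.833 for the brain list and 0.832 for the lung list (mix array 1), and 0.925 for Ccna2, 0.866 for Col6a1, 0.884 for Mlana, 0.833 for Pparg and 0.86 for the liver list (mix array 2). The widest range of a mix value among these results was 0.35 on the log2 scale. The tumours, at 19, are too many for this test.

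The 4 mix arrays were set against other choices of 4 arrays, 100 splits in all drawn from 8855. Of these, 1, the real one, gave as many genes called higher (1179, against 594 for the highest other) and 1 as many called lower (1968, against 1274). The mix arrays correlate at 0.990 or more and were known to stand apart. The result for the real split was therefore largely fixed in advance. It does not exclude chance and does not bear on whether the mix arrays are separate pools. The highest other split had 3 of the 4 mix arrays on one side. For the number of lists called by camera with its preset correlation, chance cannot be excluded: 17 of 100 splits gave 17 or more lists, and the highest other gave 23. With an estimated correlation, 1 of 100 splits gave the real count of 9, and the highest other gave 0, which has the same limit as the gene counts. A split by the 4 tumours with low poly-A controls gave 89 genes higher and 129 lower in all the other arrays than in these 4.

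Of the lysosomal genes, 27 were higher in tumours. The array medians lay between -0.09 and 0.08, so scaling every array to one median could change little. The list's mean difference was then 1.165, which argues against an offset between array medians as the whole cause. Other effects of the submitters' normalization, which is not given, were not tested. Macrophages could account for a part, since C1qc rose by about as much as the lysosome list's median, while Lyz2 and Itgam fell. Cd68 rose by about as much too. Whether its rise came from macrophages or went with that of the lysosomal genes was not tested. In 8 tumours the macrophage list's median was no higher than the highest mix array, and in all 8 the lysosome median lay above every mix array. That count is void as a test, since its bound of 10 tumours could not be reached with 8 that qualified and the macrophage median is taken over markers that moved both ways. Macrophages therefore stay open as a source, since the mix holds tissues with macrophages of their own. An untested effect of the fusion on these genes stays open too. The series holds no mesenchymal cells or tumours without the fusion. The origin of the tumour cells and the fusion therefore cannot be told apart.

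Of the pigmentation genes, 4 were higher. Melanocytes bring all their abundant transcripts, but of all 12 members 7 had a difference that stayed under 1 with 2 SE added. Among them were Dct (-0.23), Tyr (0.25) and Slc45a2 (0.36). This count cannot decide whether melanocytes in the tumours are the source. How well each probe set responds is not known, nor which members melanocytes hold in abundance. The count was also chosen after 2 other summaries of the list had proved void or undecided. Without the 4 tumours with low poly-A controls the 4 raised genes still differed by a mean of 4.697 and each stayed called, which argues against whatever set these 4 apart as the cause. Pmel (0.97 ± 0.60) was not decided by the count of members under 1. Melanocytes in the tumours stay open as a source, as does expression of these genes by the tumour cells themselves, an untested hypothesis.

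Skeletal muscle transcripts varied widely among tumours. The SD of the list's mean within the 15 tumours was 0.993 of that over the 19, which argues against whatever set the 4 tumours with low poly-A controls apart as the cause. The 20 muscle genes had a median pairwise r of 0.802, with a lowest of -0.015, so most but not all went up and down together, and muscle tissue taken with some tumours is a candidate explanation. Muscle differentiation of tumour cells predicts the same correlation and was not told apart; of 6 myogenic genes named after their values were seen, Myod1 (r = 0.431), Myog (0.409), Myf5 (0.478), Myh3 (0.394) and Myh8 (0.473) went with the list in part and Pax7 (-0.052) did not, with SDs of 0.20 to 0.71 against 1.65 for the list.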

How the results depend on the processing

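The settings on level, low poly-A controls, low 18S values and largest SD were chosen after the data were seen. Leaving out each array in turn gave 1133 to 1201 genes called higher, 1939 to 1989 called lower and 17 lists called each time. The count of relations that passed ran from 0 to 4, the 4 without tumour 17. Counts moved by over 1.5 times with the mix averaged to 1 sample (784 higher), no fold threshold (5964 higher, 3893 lower), a threshold of 2 (308 and 968), and only genes whose level reached 8 in the higher group (718 and 550; fewer genes were tested). For the last, 10 lists were called, the endothelial mean became -0.39 and was not called, and the receptor tyrosine kinase mean turned to 0.093. The level used there is a lower bound, which leaves out more of the genes lower in tumours. The cause was not tested beyond the smaller lists. With an estimated correlation 9 lists were called and the endothelial list, at -1.08, was not; fry, which does not compare a list with other genes, called 28, the angiogenic list (0.42) among them. With scores as mean log2 values 1 relation passed. The median SD among tumours moved to 0.309 and 0.312 with the probe set of largest interquartile range and largest SD, which select variable probe sets, and to 0.212 without the 7 tumours with low 18S values. The other settings kept both gene counts within 1.5 times, and those that also tested lists kept the lysosome list and the cell cycle list on the same side of the threshold; lists were not tested with a variance trend, array weights, the rank-sum test, the averaged mix, other fold thresholds or the random block. No gene called in both had its sign changed in any setting. The tumours and mixes that share the numbers 1, 2 and 4 deviate together at -0.11, 0.02 and 0.02, so the numbers pair nothing; with the replicate block over these 3 numbers 1233 genes were higher and 1966 lower and 14 lists were called, those of pericytes (adjusted p = 0.218), vesicle trafficking (0.111) and adipose tissue (0.0889) not. Of the named genes, 8 then lost their call (Adipoq, Col18a1, Dkk3, Flt4, Gbp3, Met, Myl2 and Ube2c) and 4 gained it (Acta1, Rab27b, Sytl2 and Tbx1). There were, with a random block, 1177 genes higher and 1971 lower. Pseudocounts, quantile normalization and the filter at the 75th percentile were not run on centred values, and no filter is the main setting. Signal over background may limit the size of large decreases, which was not tested.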

Other observations

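These genes were singled out after their values were seen, apart from Xist and those named for their SD among tumours; no tests of explanations were made here.

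Several genes outside the lists split the tumours. Hsd3b6, a steroid dehydrogenase gene, ran from -4.43 to 4.09 among tumours, lying over 1 above every mix array in 10 and over 1 below in 7. Synpr, a synaptic vesicle gene, lay over 1 above the mix in 8 tumours and below in 6. Tbx1, a T-box transcription factor gene, lay over 1 above the mix in 11 tumours and reached 5.64. Amtn, which encodes an enamel protein, lay above every mix array in 19 of 19 tumours and over 1 above in 9, with a median of 0.17 and a highest value of 8.09. Grp, gastrin-releasing peptide, lay over 1 above the mix in 4 tumours and below in 2, and reached 7.84. Limma with its main setting called 0 of these 5 genes, and 0 had an unadjusted p under 0.05. Amtn passed with the exact rank-sum test (adjusted p = 0.00073) and with array weights by group (adjusted p = 0.0199) or per array (adjusted p = 0.0149), and Tbx1 with array weights (adjusted p = 0.00384 and 0.00179).

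Sex-linked transcripts differed between tumours. Of 4 measured, 1 was called, Xist (-2.24 ± 0.68), which lay over 1 below every mix array in 14 tumours (list adjusted p = 0.871). The Y-linked Eif2s3y lay over 1 above every mix array in 5 tumours (1, 8, 9, 10 and 16), and Uty in these and in tumours 5, 18 and 20.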
